A study of Homo sapiens with 2 samples.

How the data were processed

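ChIP-seq was carried out on AGS gastric cancer cells with stable ATF2 overexpression, per the labels. There was 1 immunoprecipitate made with an antibody against ATF2 and 1 input library made without an antibody. Per the labels' protocols, cells were fixed with formaldehyde, nuclei were lysed and sonicated, and paired-end libraries were sequenced. Per the submitters' processing notes, FastQC, Trimmomatic 0.36, STAR 2.5.3a, MACS2 2.1.0 and the hg38 genome were named, without saying which step each served. STAR is a spliced aligner. Whether the input entered the peak calling, which threshold was set and which peaks were filtered out are not given in the sources used here.

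The deposited values analysed here are 1 annotated peak list of the whole series. Per the file headers, it gives for each peak a chromosome, start, end, strand of the gene, peak number, annotation class, distance to a transcription start site, transcript, gene name and functional annotation of the gene. The positions and distances are in bp, as the authors deposited them, with no normalisation. There is no summit, height, fold enrichment, significance value or read count for any peak. The depth of the libraries is therefore unknown here, and precision is set by the number of peaks: intervals on shares cover counting error only.

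Tested on the file, the list held 10305 peaks and 0 repeated intervals. The peak numbers increased along the chromosomes up to 24095, so that the listed peaks are 42.8% of the numbers in use. Of the peaks, 10297 lay on chromosomes 1 to 22 and X and 8 on unplaced contigs. The classes were intron, exon, promoter and transcript end, with no intergenic class. The smallest width, 182 bp, was shared by 32.2% of the peaks. Gene names were matched to a reference gene table of the GRCh38.p14 assembly, which is of the same build: of 3641 names, 3191 matched by symbol, 149 by an older symbol and 7 after undoing a conversion to a calendar date. The other 294 names, with 618 peaks, were kept in counts of peaks and left out of counts of genes. Of the matched peaks, 90.7% lay inside the gene's span in the reference, and 3225 protein-coding genes had a listed peak.

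A promoter peak was a peak within 1 kb of the start site by the authors' distance. Shares are given with exact (Clopper-Pearson) binomial 95% intervals. A count of 0 is given with the share that 3 counts would make. For each of 19 gene lists fixed before the data were examined, the number of members with a promoter peak was set among 10000 random lists of the same size drawn from the 20037 protein-coding genes of the reference. The percentile is the percent of random lists with a lower count, and a list stood apart at the 97.5th percentile or above. This describes the 1 library and is not a test between conditions, and no p-value was computed. The rule was tested on simulated data with 200 lists of 30 genes per setting. With a planted excess of 1-fold (none), 2-fold, 4-fold and 8-fold, it picked out 0.5%, 5%, 37.5% and 90% of lists, so an excess of 4-fold or less is often missed.

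The genes to name were also fixed before the data were examined. They were ATF2, HSPH1 and SLC7A11, the 10 protein-coding genes with the highest promoter peaks, up to 3 members with and up to 3 without a promoter peak per list, the 5 genes with the most peaks, and the 5 highest peaks anywhere. The plan ranked peaks by fold enrichment, significance or score. Since the list has none of these, peak width (end minus start) was used instead, a choice made after seeing the file. Other genes named were chosen after their values were seen. Some genes that the rule takes are not reported here.

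Alternatives planned beforehand and run were windows of 500 bp and 3 kb, the authors' promoter class, gene names as the authors wrote them, chromosomes 1 to 22 and X only, and merging of peaks within 500 bp. Added after seeing the data were random lists matched on gene length in 20 bins, and results without the first 48 Mb of chromosome 5 and the first 40 Mb of chromosome 3. Also added were 7 marker lists for blood, stromal and squamous cells, 30 abundant housekeeping transcripts, a second list of 30 neutrophil genes, a group of housekeeping complexes, and counts per term of the authors' functional annotation with at least 20 genes, among random draws with and without matching on gene length. Planned searches for the cAMP response element, AP-1 and control motifs, random genomic positions as background, lists matched on CpG content and an own annotation of classes need a genome sequence or full gene models, which were not used here. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.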

Results

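AGS is a human gastric adenocarcinoma cell line, and the cells studied here stably overexpressed ATF2. ATF2 is a leucine zipper transcription factor that stress-activated kinases phosphorylate and that binds DNA as a dimer, often with JUN. Chromatin was crosslinked, sheared and precipitated with an antibody against ATF2, and the recovered DNA was sequenced (ChIP-seq). The labels describe 1 ATF2 immunoprecipitate and 1 input library, sequenced without precipitation. The measurement was the authors' annotated list of peaks, intervals of the hg38 genome with an excess of reads. The list gives each peak's position, gene and distance to a transcription start site, with no read count, fold enrichment or score. The read depth of either library is therefore unknown here. With 1 library of each kind there was no replicate check, no test between groups was run, and all intervals are exact binomial 95% intervals that cover counting error only.

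The first question was where in the genome ATF2 peaks were listed. Most of them lay inside genes, far from the start site. Of 10305 peaks, 8772 were in introns (85.1%, 95% interval 84.4 to 85.8) and 769 in exons (7.46%, 6.96 to 7.99). A further 685 carried the authors' promoter class (6.65%, 6.17 to 7.15), and 79 lay at transcript ends (0.767%, 0.607 to 0.955). No peak had an intergenic class, and 260 of the 262 peaks placed upstream of a start site reached that site. Of the peaks whose gene name matched the reference, 90.7% lay inside that gene. The peaks carry numbers up to 24095, of which 13790 do not appear in the list. The median width was 220 bp (quartiles 182 and 290 bp). Promoter-class peaks were wider, with a median of 252 bp against 216 bp for intronic peaks, and 8.32% of them had the smallest width against 34.3% of the intronic peaks.

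A small part of the peaks lay near start sites. Of all peaks, 601 lay within 1 kb of an annotated start site (5.83%, 5.39 to 6.30), and 431 of those, 71.7%, lay within 250 bp. Upstream peaks were listed almost only where they reached the start site, so the 261 upstream promoter peaks lie close to it by the make-up of the list. Of the 340 at or downstream of the start site, 177 lay within 250 bp (52.1%). The promoter peaks belonged to 523 protein-coding genes, 2.61% of the 20037 in the reference, and 7 genes had more than 1. The promoter share depended on the window and on the dense stretches described further on. It was 4.88% within 500 bp, 7.51% within 3 kb and 7.63% outside those stretches.

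**Figure D1:**
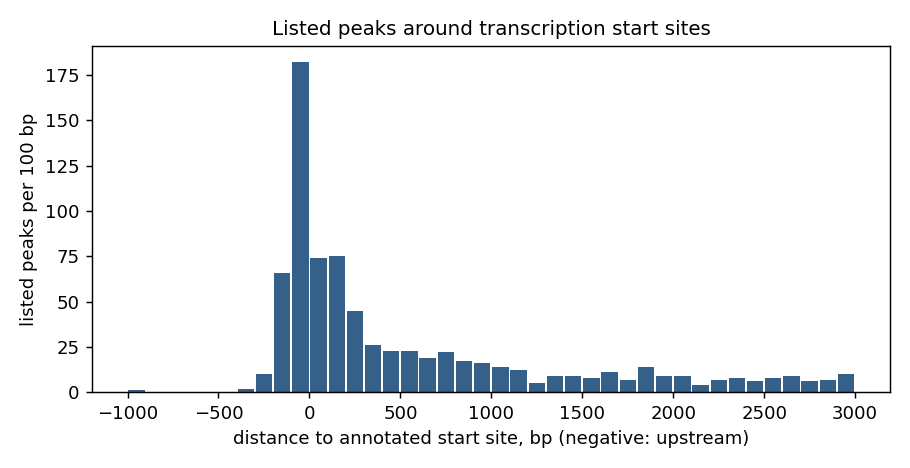
Number of listed peaks per 100 bp (vertical axis) by distance to the annotated start site in bp (horizontal axis, negative values upstream), for the 1 peak list of the ATF2 immunoprecipitate. The fullest bin, the 100 bp just upstream of the start site, holds 182 peaks, and the bin just downstream holds 74. Upstream peaks are listed almost only where they reach the start site.

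The factor itself and both genes named beforehand for this cell model had listed peaks. Of all protein-coding genes in the reference, 16.1% had a listed peak and 2.61% a promoter peak. HSPH1, a heat shock chaperone of the HSP110 family, had a promoter peak on chromosome 13 from 31162322 to 31162573, 59 bp upstream of the start of transcript ENST00000445273. SLC7A11, the cystine transporter that feeds glutathione synthesis and restrains ferroptosis, had 1 peak in intron 2 of 11, on chromosome 4 from 138235532 to 138235748. That peak lay 6709 bp from the start site and did not count as a promoter peak. ATF2 had 2 intronic peaks on chromosome 2, from 175117890 to 175118454 in intron 5 and from 175121351 to 175121673 in intron 4. No peak was listed in an ATF2 exon or at its promoter.

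The widest promoter peak belonged to GPR108, on chromosome 19 from 6737221 to 6738013, 14 bp upstream of the start site. Peak width ranked the genes here because the list has no enrichment value, and width does not measure enrichment. Next came EIF3B, a subunit of translation initiation factor 3, with a peak 776 bp wide, and WDR74, a ribosome assembly factor, with 775 bp. The phosphatase gene CDC25C, whose product drives entry into mitosis, had a promoter peak of 745 bp, and the transcriptional repressor gene CIC had one of 739 bp. HNRNPL (691 bp), RFX1 and NGDN (677 bp each), GET3 (673 bp) and ANKRD1 (659 bp) completed the first 10. Of these 10 genes, GPR108, CIC, HNRNPL, RFX1 and GET3 are on chromosome 19. On that chromosome 59.3% of the 113 listed peaks were promoter peaks (49.6 to 68.4). Few of its long genes had a peak, 3 of 32 of at least 100 kb. Counted per gene, 61 of its 1451 protein-coding genes had a promoter peak (4.20%, 3.23 to 5.37), against 2.61% of all protein-coding genes.

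Which groups of genes had promoter peaks was asked with 19 gene lists. Against random protein-coding genes, lists of the protein synthesis machinery and of chromatin packaging stood apart, as did the transcription factor family of ATF2. Of 36 cytosolic ribosomal protein genes, 10 had a promoter peak (27.8%, 14.2 to 45.2), where random lists of the same size averaged 0.94. Of 63 core histone genes, 9 had one (14.3%, 6.75 to 25.4), against an average of 1.64. None of the 10000 random lists reached either count. Of 32 ATF, CREB and AP-1 family genes, 4 had a promoter peak (12.5%, 3.51 to 29.0), a count that 94 random lists reached. A list of 30 genes was named for the cAMP response element, the DNA element that ATF2 and CREB bind. Of these, 4 had a promoter peak (13.3%, 3.76 to 30.7), and 70 random lists reached that count. The element itself was not searched for in the genes or the peaks. FOS and JUN are in both of these lists. The intervals of both lists include the share of 124 genes of housekeeping complexes (8.06%), against which neither list was tested. The 4 lists also stood apart when the random lists were matched on gene length. With a window of 500 bp the cAMP response element list had 3 members, at the 97.36th percentile, and no longer stood apart.

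RPS14 and RPL27 were among the ribosomal protein genes with the widest promoter peaks. The RPS14 peak lay on chromosome 5 from 150449569 to 150450040, 48 bp upstream of the start site. RPL18, RPL6, RPL8, RPLP0, RPS6 and RPL23 also had promoter peaks, while RPL10A, RPL11 and RPL12 had none. Of the 10 peaks, 6 lay within 250 bp of the start site, and those of RPL6, RPL23 and RPS6 lay 729 to 825 bp downstream of it. Among the core histone genes, the replication-dependent H4C3, H2BC5 and H2BC12 of the chromosome 6 cluster had the widest promoter peaks. The H4C3 peak ran from 26103609 to 26104139, 2 bp upstream of its start site. H4C2, H4C8, H4C12, H2AC11 on chromosome 6 and H4C14 and H2AC20 on chromosome 1 also had one, and H2AC1, H2AC12 and H2AC13 had none.

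In the ATF, CREB and AP-1 family, the genes with promoter peaks were ATF7, the closest relative of ATF2, and JUND, FOS and JUN, which encode AP-1 subunits. All 4 peaks lay within 250 bp of the start site. The ATF7 peak was on chromosome 12 from 53625994 to 53626402, 209 bp downstream of the start site. The JUN peak was on chromosome 1 from 58783996 to 58784230, 214 bp downstream, and the FOS peak on chromosome 14 from 75278524 to 75278784, 120 bp upstream. ATF1 had no listed peak, and ATF2 and ATF3 had intronic peaks only. The ATF3 peak, 786 bp wide, lay 30991 bp from the annotated start site. In the cAMP response element list, CRTC2, a CREB coactivator, and the neuronal activity gene NPAS4 joined FOS and JUN. BDNF and CCNA2 had no promoter peak.

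**Figure D2:**
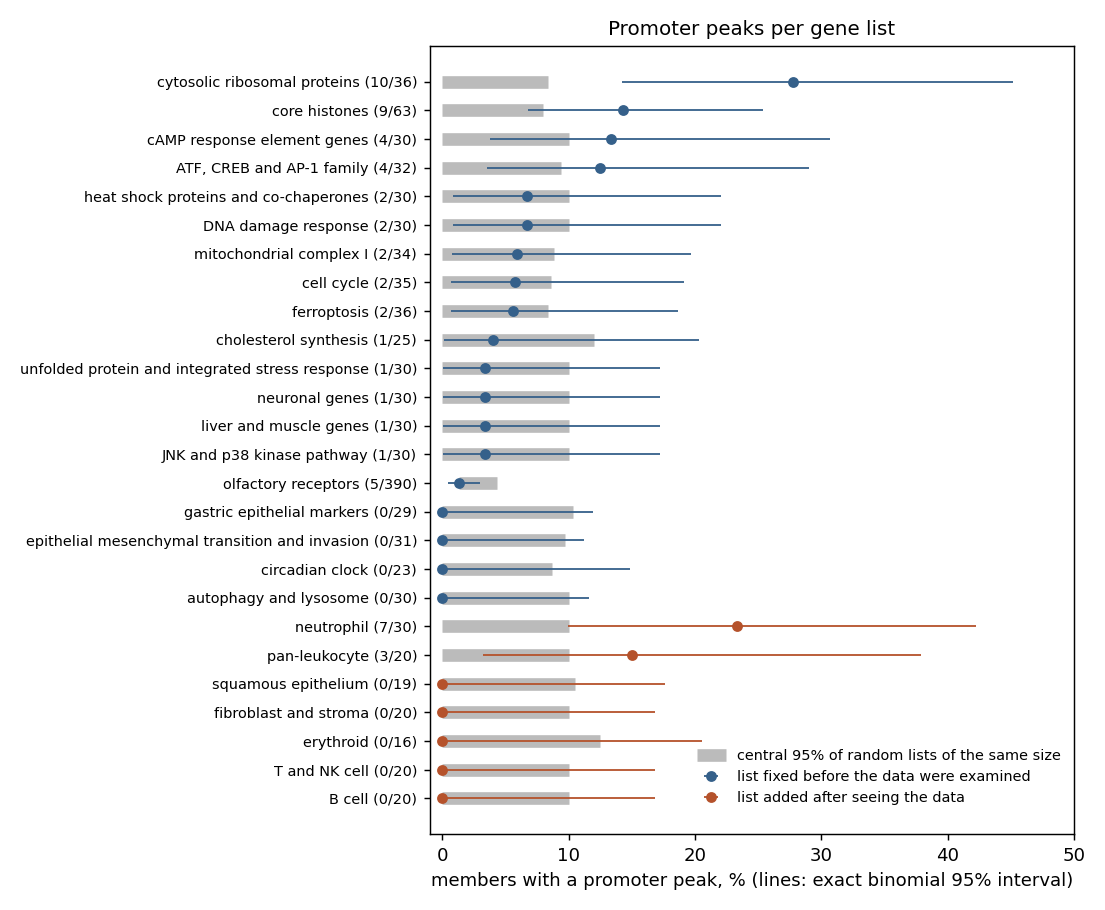
Percent of members with a listed peak within 1 kb of a start site (horizontal axis) for each gene list (vertical axis, members with a promoter peak over all members), with exact binomial 95% intervals as lines and the central 95% of 10000 random lists as grey bars. Ribosomal protein genes (27.8%) and core histone genes (14.3%) lie to the right of the random range, as do the ATF, CREB and AP-1 family (12.5%) and the cAMP response element genes (13.3%), and of the lists added after seeing the data (orange) the neutrophil (23.3%) and pan-leukocyte (15%) genes.

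The other 15 lists did not stand apart. In the ferroptosis list 2 of 36 members had a promoter peak, the ferritin heavy chain gene FTH1 and the polyamine enzyme gene SAT1, and ACSL3, ACSL4 and AIFM2 had none. The heat shock list had HSPH1 and the co-chaperone gene STIP1 among 30 members, with AHSA1, BAG3 and CDC37 lacking a promoter peak. These lists stood apart with a 3 kb window, at the 97.68th and 99.98th percentiles. The cell cycle list had CDC25C and TOP2A among 35 members, and AURKA, AURKB and BUB1 had none. In the DNA damage list 2 of 30 members had a promoter peak, BRCA1 among them, and ATM, ATR and BRCA2 had none. The JNK and p38 list had only DUSP10, a phosphatase of these kinases, and the unfolded protein list only MANF, each among 30 members. DUSP1, DUSP16 and DUSP4 in the former and ASNS, ATF4 and ATF6 in the latter had no promoter peak. The complex I list had NDUFB3 and NDUFB1 among 34 members, without NDUFA1 and NDUFA10. Cholesterol synthesis had MSMO1 among 25, without CYP51A1 and DHCR7.

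No promoter peak was listed in 4 of the lists. These were 31 genes of epithelial-mesenchymal transition and invasion (CCN1, CCN2 and CD44 among them), which allows a share of up to 9.68% by a limit of 3 counts and up to 11.2% by the exact interval, and 29 gastric epithelial markers (ANXA10, ATP4A, ATP4B), which allows up to 10.3% or 11.9%. The 30 autophagy and lysosome genes (ATG12, ATG13, ATG14) allow up to 10% or 11.6%, and the 23 circadian clock genes (BHLHE40, BHLHE41, BMAL1) up to 13.04% or 14.8%. In the comparison lists, STMN2 was the only one of 30 neuronal genes with a promoter peak (CALB1, CAMK2A and DCX had none), and SERPINA1 the only one of 30 liver and muscle genes (ACTA1, AHSG and ALB had none). Of 390 olfactory receptor genes, 5 had one (1.28%, 0.418 to 2.97), with OR52I2, OR4C5 and OR4F5 the widest, and OR10A2, OR10A3 and OR10A4 had none.

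Exon peaks were frequent in heat shock genes and in genes of epithelial-mesenchymal transition and invasion. Of 30 heat shock genes, 8 had an exon peak, where lists matched on gene length averaged 0.59, and of 31 transition and invasion genes 8 had one, against 0.95. None of the 10000 matched lists reached either count. Of 30 abundant housekeeping transcripts, a list added after seeing the data, 8 also had an exon peak, against 0.50. The heat shock and invasion genes included HSP90AA1 and HSP90AB1, which encode the cytosolic HSP90 chaperones, the growth factor gene CCN2 and the intermediate filament gene VIM. All were chosen after their values were seen. In HSP90AB1, for example, a peak of 785 bp was annotated to exon 5 of 12, on chromosome 6 from 44249733 to 44250518. Beside these counts stands that of neutrophil genes, a list added after seeing the data: 12 of 30 had a listed peak, 8 had an exon peak and 7 a promoter peak. Of 20 genes in a broader leukocyte list, also added, 9 had a listed peak and 3 a promoter peak.

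Peaks were spread very unevenly along the chromosomes. The first 48 Mb of chromosome 5, which reach to the centromere, held 1876 peaks, 18.2% of the list. Per Mb covered by genes this was 85.1 peaks, against 4.58 on the rest of the chromosome, an 18.6-fold difference. The first 40 Mb of chromosome 3 held 858 peaks, or 34.7 per gene-covered Mb, against 1.72 between 40 and 98 Mb and 12.3 beyond, 20.2-fold and 2.81-fold differences. Both stretches were picked out after seeing the data. In the chromosome 5 stretch, 37 of 41 protein-coding genes of at least 100 kb had a peak (90.2%, 76.9 to 97.3), against 84 of 181 on the rest of the chromosome (46.4%, 39.0 to 54.0). Promoter peaks made up 0.906% of the peaks in that stretch (0.529 to 1.45) and 6.88% on the rest of the chromosome (4.46 to 10.1). Counted per gene the promoter peaks were not fewer: of the 167 protein-coding genes in the stretch 9 had a promoter peak (5.39%, 2.49 to 9.98), against 21 of 737 on the rest (2.85%, 1.77 to 4.32), with overlapping intervals.

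The genes with the most peaks lay in these stretches. CDH18 and CDH12, which encode neuronal cadherins (cell adhesion proteins), had 236 and 223 peaks, and the catenin gene CTNND2 had 134, all on chromosome 5. On chromosome 3, the contactin gene CNTN4 had 116 and the glutamate receptor gene GRM7 had 111. CDH18 covers 1104418 bp and held 214 peaks per Mb. The widest peaks of all lay elsewhere with 1 exception. They were in intron 6 of IL18RAP, a subunit of the interleukin-18 receptor (2027 bp, chromosome 2 from 102438775 to 102440802), and in intron 4 of SPI1, the myeloid transcription factor PU.1 (1819 bp, chromosome 11 from 47355960 to 47357779). LRRFIP1 (1399 bp), ANKRD36B (1342 bp) and CDH18 (1207 bp), all intronic, followed.

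**Figure D3:**
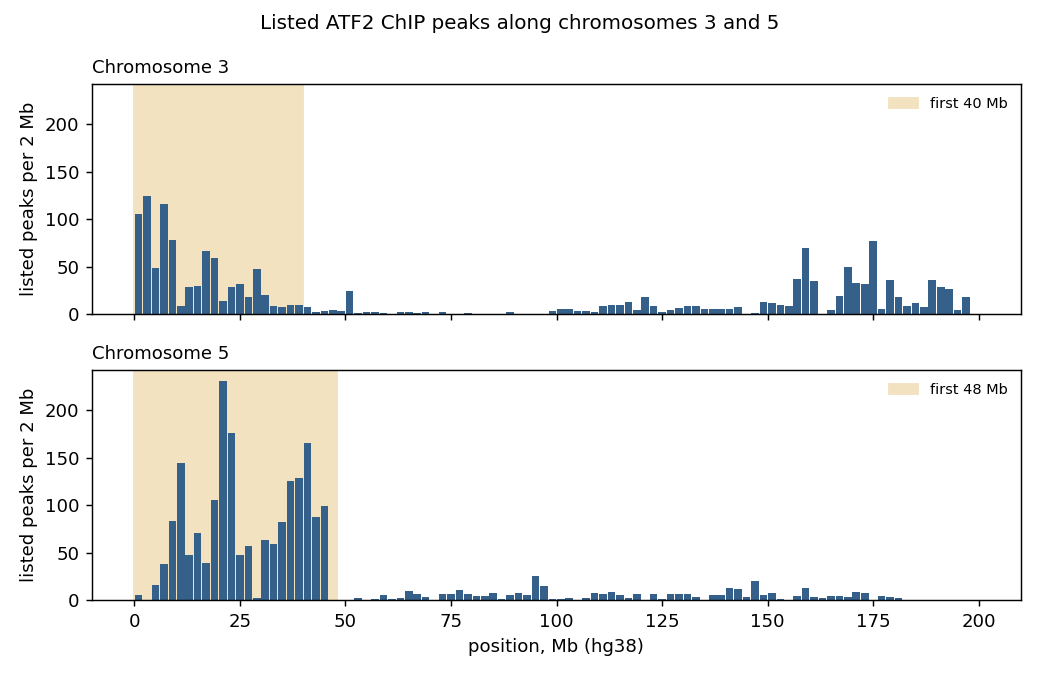
Listed peaks per 2 Mb window (vertical axis) along chromosomes 3 and 5 (horizontal axis, Mb of hg38), from the 1 peak list, which has no intergenic class. The shaded first 40 Mb of chromosome 3 hold 858 peaks and the shaded first 48 Mb of chromosome 5 hold 1876, with up to 231 peaks in a window.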

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

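The tests of evenness, gene-poor surroundings, abundant transcripts and the second neutrophil list and the first bound for housekeeping complexes were chosen before their results were seen, and the other tests in this part after. Binding that differs between conditions cannot be weighed, since the design has 1 immunoprecipitate.

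Of the listed peaks, 8 lay on 3 unplaced contigs, which the comparisons by chromosome leave out. They were picked up because 8 peaks exceed the limit of 3 that a count of 0 allows. No explanation was tested for them.

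The first 48 Mb of chromosome 5 held 85.1 peaks per gene-covered Mb. Binding to cadherin genes as a class is argued against: 2 of 18 cadherin genes outside the stretch had a peak, the 0.27th percentile of lists matched on gene length, although all 5 inside had one, with 573 peaks. An excess of reads over the whole stretch may account for part of the density. A regional gain of DNA copies not removed by the input would give such an excess. The peak numbers missing from the list, which run along the chromosome, were dense there too: 4358 in the stretch against 441 on the rest. Divided by the Mb outside genes this was 168 against 7.71, 21.8-fold. Whether the missing peaks lay outside genes is not given. The variance of peak counts over the 41 genes of at least 100 kb was 15.1 times the even expectation (upper simulated bound 1.48). Whether the same excess of reads at every position would be enough cannot be told from this. The bound took peaks to fall evenly by gene length, and no such ratio was computed for genes outside the stretch. Peaks were denser where fewer genes lay nearby (Spearman rho across the 41 genes, which are not independent replicates, -0.41, against -0.15 across 3310 long genes elsewhere). Gene-poor surroundings alone did not bring such a density. The stretch has 167 protein-coding genes in 48 Mb. Chromosomes 13 (338 in 114 Mb), 18 (269 in 80.2 Mb) and 4 (770 in 190 Mb) held 1.00, 0.98 and 2.16 peaks per gene-covered Mb. The first 40 Mb of chromosome 3, with 184 such genes, held 34.7. A part for gene-poor chromatin within the stretch stays open beside copy number.

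Gene length alone did not give the promoter peaks at ribosomal protein and core histone genes. Both lists stayed at the 100th percentile among lists matched on gene length. Such matching cannot tell promoter peaks from an excess of peaks anywhere in these short genes. Counted for any listed peak, 9 core histone and 12 ribosomal protein genes had one, where matched lists averaged 1.51 and 1.86. Promoters of housekeeping complexes in general were tested with 124 genes of the mitochondrial ribosome, proteasome and chaperonin, of which 10 had a promoter peak (8.06%, 3.94 to 14.3; 3.63 expected, 99.59th percentile among matched lists), so such a preference may be part of the pattern. The upper bound narrowly missed the lower bound of the ribosomal protein share (14.2%), so the list was also set among random draws from both groups together, where it stood at the 99.58th percentile. The core histone list stood at the 86th percentile of such draws, so for histone genes a general preference for active housekeeping promoters remains a candidate explanation. No such draws were made for the ATF, CREB and AP-1 family or the cAMP response element genes, so that preference stays open there too. Binding of ATF2 to these promoters and unspecific recovery of very active promoters stay open, since no enrichment over the input was analysed here. Reads from abundant transcripts, raised below for other genes, were not weighed for the ribosomal protein genes.

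Peaks at neutrophil genes included S100A8 and S100A9, among the most abundant neutrophil transcripts (1 and 2 peaks), MNDA (7) and NAMPT (16). The 50 neutrophil and pan-leukocyte genes together stood at the 100th percentile of lists matched on gene length (21 with a peak, 4.99 expected). Both lists were added after seeing the data, so this percentile cannot weigh gene length. Gene length alone is argued against only by the second neutrophil list that follows, which was also set among matched lists. Leukocyte-derived material among the reads is a candidate source: of a second list of 30 neutrophil genes, none in the first lists, 14 had a peak (4.06 expected, 100th percentile), while 3 of 20 T and NK cell, 2 of 20 B cell, 1 of 16 erythroid, 2 of 20 fibroblast and 1 of 19 squamous genes had one, none of which stood apart. Reads from abundant transcripts of any cell could add to it, since 8 of 30 abundant housekeeping genes, among them ACTB, EEF1A1 and PKM, had an exon peak (0.50 expected, 100th percentile). Of the 83 peaks at the leukocyte genes, 34.9% were exon peaks, against 8.72% elsewhere outside the dense stretches. These 2 shares are not matched on gene length, and NAMPT, PTPRC and LCP1 alone held 16, 14 and 11 of the 83 peaks. Leukocyte-derived material and abundant transcripts both stay open, as does binding in AGS cells, whose expression of these genes was not analysed here. Of the 30 neutrophil genes, 1 is also in another list.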

How the results depend on the processing

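The count of peaks and the count of genes with a promoter peak stayed within 1.5 times under the alternatives run. The genes were 456 within 500 bp, 629 within 3 kb, 486 with the authors' names and 509 without the dense stretches of chromosomes 3 and 5 (an alternative added after seeing the data), against 523. The promoter share, 5.83%, moved to 4.88% within 500 bp, 7.51% within 3 kb, 6.65% by the authors' class and 7.63% without the dense stretches. The first 2 follow from the width of the window and the last from leaving out stretches where promoter peaks are a small share of many peaks. The authors' class also reached beyond 1 kb, as for an HSP90AA1 peak 1902 bp from the start site, so its larger share goes with a wider window too. The intron share moved from 85.1% to 81.5% without those stretches. Of 76 alternatives for the list percentiles, 73 kept their side of the threshold. The exceptions were the cAMP response element genes within 500 bp (97.36) and, within 3 kb, ferroptosis (97.68) and heat shock (99.98), and the cause was not tested. All 57 alternative counts of members stayed inside the interval of the main count. These intervals are wide, so this says little: the heat shock count went from 2 to 6 of 30 within 3 kb and stayed inside. Stricter thresholds, ranking by enrichment, summits, an own class annotation, CpG-matched lists and motif shares were not run, because the list holds no such values and no genome was used here. No paired analysis was possible because there is 1 library per group and no result comes from a test between them. Depth limits cannot be given without read counts.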

Other observations

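All counts in this part were made after seeing the data. By the authors' functional annotation, 27 of 455 annotated genes with a promoter peak carried the term translation (5.93%, 3.95 to 8.52), against 0.83% of the other annotated genes with a listed peak. Mitochondrial proteins made up 10.8% against 4.33%, and structural constituents of the ribosome 4.62% against 0.48%. These differences shrank with matching on gene length. Without matching, 5 of 155 terms were reached by fewer than 5 of the 10000 random draws and 4 were as low in fewer than 5. The 155 include an entry without a term name, which passed neither bound. With draws matched on gene length, 0 terms passed either bound. Translation then had 19.7 genes expected against 27 (68 draws reached it), mitochondrion 35.6 against 49 (12 draws), and structural constituent of ribosome 17.1 against 21 (833 draws). Integral component of membrane had 104 expected against 82, with 7 draws as low. Protein kinase activity had 9.82 expected against 7, with 2038 draws as low.

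Counted for any listed peak, 6 of the 19 lists fixed beforehand stood apart from random lists matched on gene length. Besides the 4 lists with promoter peaks above, heat shock genes (12 of 30) and unfolded protein genes (9 of 30) did so, where matched lists averaged 2.68 and 3.85. The ribosomal protein genes had 12 of 36, against 1.86. Of 30 liver and muscle genes 1 had a listed peak, where matched lists averaged 3.29. Of 390 olfactory receptor genes 9 had one, where matched lists averaged 17.9.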
